A study of Cephalotaxus fortunei with 9 samples.

How the data were processed

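Poly(A)-selected RNA from leaf, root and stem of Cephalotaxus fortunei, an East Asian conifer known for cephalotaxine-type alkaloids, was sequenced in 9 libraries, 3 per tissue. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I, and made into strand-specific libraries after poly(A) enrichment. The labels do not say whether libraries of a tissue came from separate plants, so the p-values measure the spread between these samples, which may be technical in part.

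Per the submitters' processing notes, the authors used fastp 0.23.2 and Salmon 1.10.0; the origin of the reference transcripts and the Salmon options are not given in the sources used here. Each deposited table lists 37051 transcripts with a length, an effective length, a TPM (length-scaled abundance, summing to 1000000 in each library) and an estimated count of reads, per the file headers. Transcript names and lengths were identical in the 9 tables. The deposited estimated counts differed from a whole number by more than 0.001 in 39.6% to 50.3% of transcripts, because reads that match several transcripts are divided among them. Values of near-identical transcripts are therefore uncertain, and a transcript at 0 may share its reads with such a copy. In 6.84% to 11.8% of transcripts the effective length was above the length. Transcripts carry running numbers only, and the files do not pair these with gene names or sequences. The 17 gene lists fixed in advance (photosynthesis, lignin, cytochrome P450, alkaloid-type enzymes, markers of other cell types and others) therefore gave 0 testable lists, and coordinates were not used here.

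Library totals were 12809484 to 14606814 estimated reads in leaf, 7117807 to 8093638 in root and 18417327 to 19652495 in stem. Root replicates 1 and 2 differed by less than the sampling noise (chi-square statistic per degree of freedom 0.527 over 19407 transcripts with at least 20 reads in the pair, against 14.6 to 19.1 within leaf and 15.8 to 17.4 within stem). They were averaged and counted as 1 sample, a choice made after the data were seen. The main model thus held 8 samples: 3 leaf, 2 root and 3 stem. The design fixed before the data were examined named 9 separate libraries; that planned fit is given as an alternative.

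Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filtering by expression within tissue groups (24564 transcripts kept), TMM scaling, and the robust quasi-likelihood test with 1 mean per tissue and no further term. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 fold change of at least 1. An F test over the 3 tissues used the adjusted p alone. A transcript was termed root-highest, leaf-highest or stem-highest when it was called higher in that tissue than in each of the other 2, and root-lowest, leaf-lowest or stem-lowest in the converse case. Overlaps of this kind share libraries, so they were also computed in 20 simulated data sets without tissue effects. Transcripts to be named were fixed by rule before the data were examined: the 2 root-highest and 2 root-lowest transcripts with no overlap between libraries, at least 10 TPM in the highest tissue, and the largest value of the smaller of their 2 fold changes. A fold against samples without a read was computed against a floor of 3 reads over the group. The floors cover counting error only. The bootstrap interval given below comes from resampling transcripts and covers the spread among them only.

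The pairwise counts of calls, the tissue groups and the named transcripts were recomputed with DESeq2 1.42.0, limma 3.58.1 (voom on counts, and log2 of TPM with pseudocounts of 1 and 0.1), other scalings and filters, a threshold test against a fold of 1.5, only the libraries of the tissues compared, a replicate block, and each library left out in turn. Effective-length offsets and root replicate 3 alone as root were added after the data were seen. The count from the F test was recomputed under part of these settings, and the counts of called transcripts at 4-fold and 32-fold, with 0 reads, or below 1 TPM in the other tissues were not recomputed under them. Estimated correlations for gene lists and their blocked fits could not be run without names. The number of transcripts at 1 TPM or more and the share of TPM in the 100 most abundant transcripts were compared by two-sided exact permutation tests on samples.

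The model was tested on simulated counts for 24564 transcripts with 200 changed at a mean of at least 1 CPM. A transcript counted as found at an adjusted p under 0.05 alone, without the fold threshold. Far fewer transcripts were changed than were called in the data, so these rates do not carry over to the real comparisons. In the simulated leaf-against-stem comparison, 12% of 2-fold and 43% of 4-fold changes were recovered, and 4 of 59 transcripts found were false (6.78%). For leaf against root, 8% and 31% were recovered, and 2 of 41 found were false (4.88%). For stem against root, 11% and 41% were recovered, and 3 of 55 found were false (5.45%). The median fitted log2 change of the 4-fold transcripts was 1.94, 1.95 and 2.00 in these 3 simulations.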

Results

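Transcript abundance was measured in leaf, root and stem of Cephalotaxus fortunei, in a study of the enzymes that make its cephalotaxine and homoerythrina alkaloids. The series text states that expression across the tissues was used for network analysis and to select candidate sequences. Leaf and stem were represented by 3 libraries each. Root had 3 libraries of which replicates 1 and 2 held nearly the same values: 41.4% of 5744 transcripts with whole read numbers were equal, compared with 2.08% to 3.08% in the other pairs of libraries of a tissue that were examined. These 2 root libraries were counted as 1 sample, which left 2 root samples. The files give transcripts by number only, so groups of transcripts are described by their tissue profile and not by function.

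The 3 tissues had separate transcriptomes, and root stood furthest apart. Spearman correlations across transcripts were 0.917 to 0.922 between leaf libraries and 0.913 to 0.915 between stem libraries. They were 0.808 to 0.819 between leaf and stem, 0.511 to 0.629 between leaf and root, and 0.478 to 0.619 between stem and root. Root replicate 3 correlated with root replicates 1 and 2 at 0.731, lower than leaf with stem. These correlations are across transcripts, which are not independent replicates. The first principal component held 56.4% of the variance and separated root from the shoot tissues, and the second held 27.7% and separated leaf from stem. Of 24564 transcripts tested, 17069 (69.5%) differed among the tissues (edgeR quasi-likelihood F test, adjusted p under 0.05).

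**Figure D1:**
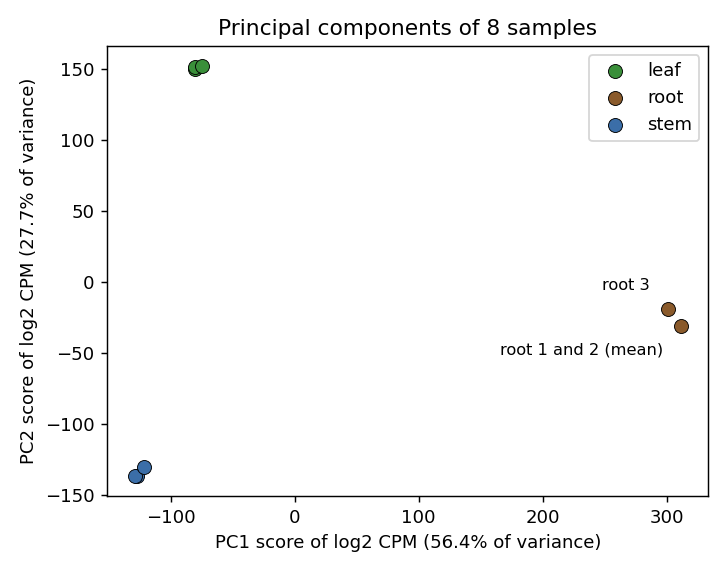
Scores of 8 samples (3 leaf, 2 root, 3 stem; 1 point each) on the first and second principal components of log2 CPM (read counts scaled to library size). Root samples lie apart from the shoot tissues on the first axis (56.4% of variance), and leaf and stem lie apart on the second (27.7%).

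The comparison of leaf with root asked which transcripts differ between the photosynthetic organ and the underground organ. Leaf and root differed in 10872 transcripts, 44.3% of those tested. Of these, 6528 were higher in root and 4344 were higher in leaf. The median absolute log2 fold change of called transcripts was 2.83, both as fitted and with transcripts at 0 reads in a tissue set to a floor of 3 reads over that tissue. With this floor, 7282 differed at least 4-fold. Differences of at least 32-fold were found for 2369 transcripts higher in root and 338 higher in leaf. Of the transcripts higher in root, 2216 (33.9%) had 0 reads in leaf, and of those higher in leaf, 199 (4.58%) had 0 reads in root. These numbers were on unequal terms. Root replicate 3 had 2606 transcripts at 0 reads, against 11305 to 12022 in each leaf library. The floor was 0.165 CPM in root and 0.065 CPM in leaf, so 32-fold over 0 reads required a higher level in leaf. The numbers were not recomputed without root replicate 3. The share of calls higher in leaf was 40.0% with both root samples, 49.6% without root replicate 3 and 47.9% with root replicate 3 as the only root sample. The median log2 fold change of all tested transcripts was -0.27 with both root samples. Over the transcripts shared with this fit it was -0.09 without root replicate 3 and -0.14 with root replicate 3 as the only root sample.

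Stem and root differed in 12784 transcripts (52.0%), the largest number among the pairwise comparisons in the fitted model. Root was higher for 7809 and stem for 4975. Without root replicate 3 the numbers were 5590 and 5111, and with root replicate 3 as the only root sample they were 6107 and 5155. The median absolute log2 fold change of called transcripts was 2.92 as fitted and 2.89 with the floor of 3 reads, and 8948 differed at least 4-fold. Differences of at least 32-fold numbered 2475 for transcripts higher in root and 508 for transcripts higher in stem. Of the transcripts higher in root, 2329 (29.8%) had 0 reads in stem, and of those higher in stem, 4.04% had 0 reads in root. As with leaf, these numbers were on unequal terms and were not recomputed without root replicate 3. The floor was 0.165 CPM in root and 0.068 CPM in stem. Stem was higher in 38.9% of calls under TMM scaling and in 23.7% with library totals alone. Library totals alone moved the median log2 fold change of all tested transcripts from -0.46 to -1.09. Over the transcripts shared with the main fit, this median was -0.23 without root replicate 3 and -0.31 with root replicate 3 as the only root sample.

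Leaf and stem, the 2 shoot tissues, differed in 7115 transcripts (29.0%). The calls were evenly divided under TMM scaling, with 3573 higher in leaf and 3542 higher in stem. The median absolute log2 fold change of called transcripts was 2.27 as fitted and 2.24 with the floor of 3 reads. Of the called transcripts, 4031 differed at least 4-fold, and differences of at least 32-fold numbered 464 higher in leaf and 473 higher in stem. Among transcripts called higher in stem, 323 had 0 reads in leaf, and among those higher in leaf, 465 had 0 reads in stem. The direction of the calls depended on the scaling: leaf was higher in 50.2% of calls with TMM and in 49.8% with DESeq2 size factors in edgeR, in 71.9% with library totals alone, and in 71.3% with limma on log2(TPM + 1). Library totals alone shifted the median log2 fold change of all tested transcripts from 0.02 to 0.57. TMM factors were 0.75 to 0.79 for the stem libraries and 1.12 to 1.14 for the leaf libraries. Calls shared with the main model numbered 6041 under library totals.

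**Figure D2:**
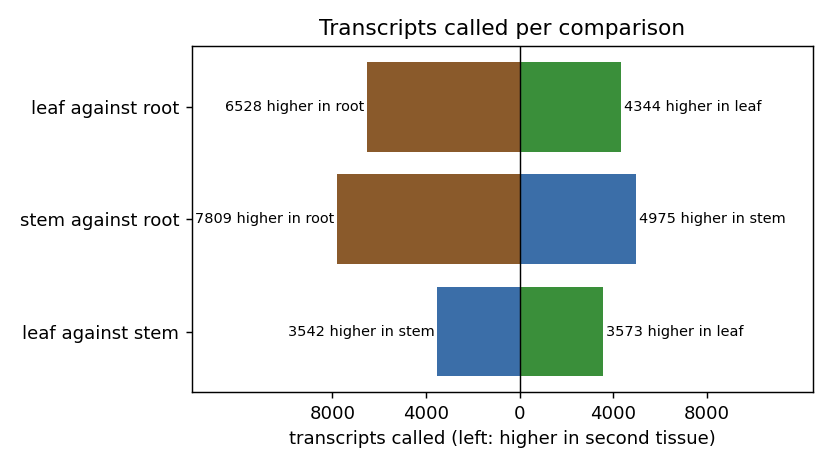
Number of transcripts called in each pairwise comparison (edgeR, adjusted p under 0.05 and absolute log2 fold change of at least 1), with bars to the right for the first tissue named and to the left for the second. With both root samples, root is the higher tissue in most calls against leaf (6528 of 10872) and stem (7809 of 12784); with 1 root sample stem is higher in 45.8% or 47.8% of calls and leaf in 47.9% or 49.6%, and leaf and stem calls divide into 3573 and 3542.

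Transcripts were next grouped by the tissue in which they were highest. The root-highest group was the largest in the main fit with 4753 transcripts (19.3% of those tested). In this group, 2557 transcripts reached at least 1 TPM in both root samples and stayed below 1 TPM in all 6 leaf and stem libraries. Of these 4753 transcripts, 2251 had a root mean of at least 10 TPM and 412 of at least 100 TPM. As a group they held 32.2% ± 3.75 of root TPM (SD, n = 2), 2.14% ± 0.0660 of leaf TPM (SD, n = 3) and 1.59% ± 0.0359 of stem TPM (SD, n = 3). The count was lower with 1 root sample: it was 3135 without root replicate 3 and 3257 with that library as the only root sample, and 2435 transcripts were root-highest in both of these fits. In each such fit the lone root sample is assumed to vary like the other tissues. Root libraries also had the lowest totals (7117807 to 8093638 estimated reads) and the lowest minimum effective length over transcripts.

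The stem-highest group held 1991 transcripts (8.11%). They were abundant in stem, with 1755 at a stem mean of at least 10 TPM and 645 at 100 TPM or more. They held 39.9% ± 0.240 of stem TPM (SD, n = 3), compared with 11.7% ± 0.0459 of leaf TPM (SD, n = 3) and 7.65% ± 0.551 of root TPM (SD, n = 2). Most were also present in other tissues: 50 reached 1 TPM in every stem library and stayed below 1 TPM in every leaf and root sample. With library totals alone, the stem-highest count was 1185.

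The leaf-highest group was smaller, with 1085 transcripts (4.42%), of which 929 had a leaf mean of at least 10 TPM and 218 of at least 100 TPM. These transcripts held 14.6% ± 0.0615 of leaf TPM (SD, n = 3), 2.18% ± 0.00718 of root TPM (SD, n = 2) and 1.98% ± 0.0610 of stem TPM (SD, n = 3). In this group 62 transcripts reached 1 TPM in every leaf library and stayed below 1 TPM in every stem and root sample. Root replicate 3 limits this count too, and it was not recomputed without that library. With library totals alone the leaf-highest count was 1700. The groups were chosen on these samples, so their shares of TPM describe them and are not independent evidence of their direction.

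**Figure D3:**
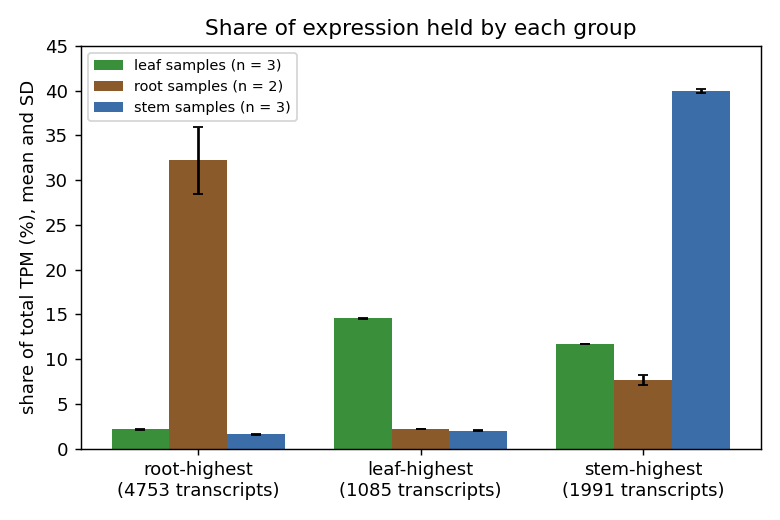
Share of total TPM (%, vertical axis, mean with SD as error bars) held in leaf (n = 3), root (n = 2) and stem (n = 3) samples by the root-highest, leaf-highest and stem-highest groups. Root-highest transcripts hold 32.2% of root TPM, leaf-highest transcripts 14.6% of leaf TPM and stem-highest transcripts 39.9% of stem TPM.

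The converse groups were the root-lowest with 2975 transcripts, the stem-lowest with 2189 and the leaf-lowest with 1548. With 1 root sample the root-lowest count was 3329 (without root replicate 3) or 3260 (that library alone), so the excess of root-highest over root-lowest transcripts was present only with both root samples. Root-lowest transcripts held 37.2% ± 0.174 of leaf TPM (SD, n = 3) and 42.5% ± 0.381 of stem TPM (SD, n = 3), against 6.79% ± 0.828 of root TPM (SD, n = 2). In the root-lowest group, 197 transcripts stayed below 1 TPM in both root samples and reached 1 TPM in all 6 shoot libraries. The corresponding numbers were 770 for the stem-lowest group and 378 for the leaf-lowest group. The root-lowest number required less than 1 TPM in root replicate 3. That library had 2606 transcripts at 0 reads, against 8705 and 8747 in root replicates 1 and 2. These numbers were not recomputed without it, so they do not rank the tissues. With library totals alone, the stem-lowest group held 4069 transcripts, and under limma on log2(TPM + 1) the leaf-lowest group held 994. Leaf-highest and leaf-lowest transcripts had median lengths of 953 and 1224 bases, and stem-highest and stem-lowest transcripts of 1055 and 852 bases. The root-highest and root-lowest medians were 1139 and 1131 bases, and the median of all tested transcripts was 1112 bases.

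Calls against leaf and against stem share the root samples. In 20 simulated data sets with no tissue effect, almost no transcripts were called in both (0 root-highest and 0.05 root-lowest on average), so these data sets do not show how far sharing adds to lists of the observed sizes. Independent lists of the observed sizes would share 2075 transcripts higher in root and 880 lower in root, against 4753 and 2975 observed. Part of the excess may come from the shared root samples, which are too few to divide.

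The 4 transcripts named by rule had reads in root or in shoot but not in both. Transcript transcripts_3707 (695 bases) stood at 2069 ± 543 TPM in root (SD, n = 2) and had 0 reads in leaf and stem. Its level was at least 24047-fold higher in root than in leaf (adjusted p = 3.65e-04, edgeR) and at least 22864-fold higher than in stem (adjusted p = 3.11e-04, edgeR). Transcript transcripts_20211 (1131 bases) stood at 1242 ± 370 TPM in root (SD, n = 2) with 0 reads in leaf and stem, at least 16498-fold and 15686-fold higher (adjusted p = 3.88e-04 and 3.31e-04, edgeR). Transcript transcripts_29270 (5515 bases) had 0 reads in root, 81.1 ± 25.02 TPM in leaf (SD, n = 3) and 86.8 ± 6.43 TPM in stem (SD, n = 3). It was at least 2261-fold higher in leaf and 3499-fold higher in stem than in root (adjusted p = 1.91e-05 and 1.18e-05, edgeR). Transcript transcripts_9624 (4047 bases) had 0 reads in root, 99.2 ± 9.56 TPM in leaf (SD, n = 3) and 104 ± 2.35 TPM in stem (SD, n = 3), at least 2164-fold and 3215-fold higher than in root (adjusted p = 8.61e-07 and 3.00e-07, edgeR). Because Salmon divides reads among similar transcripts, 0 reads on a transcript does not exclude reads on a near-identical one. Without sequences, whether transcripts_3707 and transcripts_20211 belong to the plant or to another organism in root was not tested.

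The number of expressed transcripts and the share of the most abundant ones were compared between tissues, and no comparison passed its test. At least 1 TPM was reached by 21108 ± 378 transcripts in leaf (SD, n = 3), 18189 ± 520 in stem (SD, n = 3) and 29274 ± 5085 in root (SD, n = 2). Root replicates 1 and 2 detected 25684 and 25673 transcripts, and root replicate 3 detected 32870. Thinned to 7117740 reads per library, the means were 20917 in leaf, 18083 in stem and 29195 in root. The 100 most abundant transcripts held 36.1% ± 0.694 of TPM in stem (SD, n = 3), 30.7% ± 0.451 in leaf (SD, n = 3) and 31.1% ± 4.14 in root (SD, n = 2). Two-sided exact permutation tests gave p = 0.10 (adjusted p = 0.12 over 6 comparisons) for every comparison of these 2 measures except the top-100 share of leaf against root (p = 0.80). With these numbers of samples, 0.10 is the smallest p that the tests allow.

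The number of detected transcripts varied with transcript length in a manner that set root replicate 3 apart. Among transcripts of up to 300 bases, 94.1% reached 1 TPM in root replicate 3, compared with 53.3% in root replicates 1 and 2, 48.1% in leaf and 37.7% in stem. Above 2000 bases the values were 79.4%, 75.7%, 65.4% and 61.8%. Among 7123 transcripts with at least 20 TPM in root replicates 1 and 2, root replicate 3 lay within 2-fold of the common shift for 94.1%. The shortest effective length was 18 to 19 bases in the root libraries and 40 to 49 bases in the leaf and stem libraries. The most abundant transcript of every library except root replicates 1 and 2, transcripts_2235 (406 bases, singled out after its values were seen), took 4.36% to 5.07% of leaf TPM, 4.62% to 4.82% of stem TPM, 1.53% and 1.54% in root replicates 2 and 1, and 9.50% in root replicate 3.

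**Figure D4:**
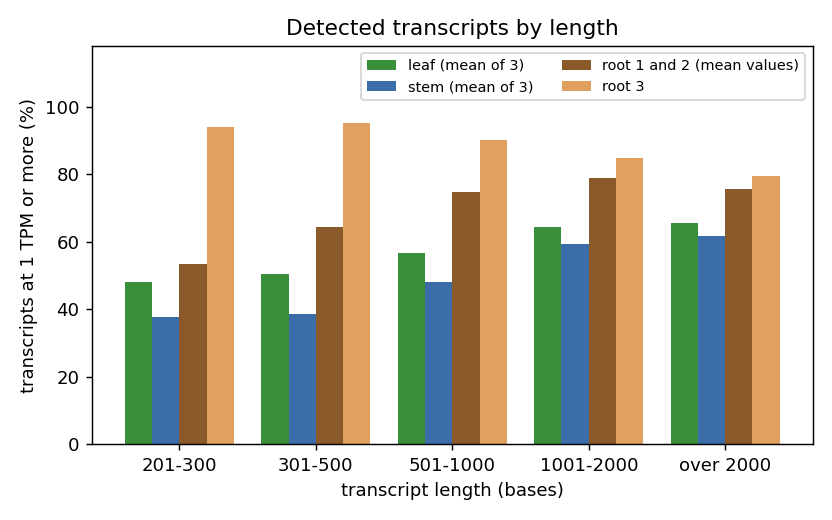
Share of transcripts (%, vertical axis) that reached 1 TPM, by transcript length in bases, for leaf and stem (means of 3 libraries), root replicates 1 and 2 (mean values) and root replicate 3. In the shortest class root replicate 3 stands at 94.1% and the other root sample at 53.3%, and above 2000 bases they stand at 79.4% and 75.7%.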

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

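The pairwise counts of calls and the count of transcripts that differ among tissues stayed within 1.5 times their main values under each alternative run, and the 4 named transcripts kept their direction and an adjusted p under 0.05 in each. Calls ranged from 9102 to 13120 for leaf against root, 10488 to 14937 for stem against root, and 6347 to 9665 for leaf against stem over the settings other than leaving out a library, and from 9315 to 10863, 10701 to 12791 and 6229 to 7114 with a library left out. The fits without root replicate 1 or 2 keep the same root sample, since these are counted as 1, and so test little; they give the upper ends of these ranges. Groups by tissue depended on scaling. Under limma on log2(TPM + 1), leaf-highest, leaf-lowest, stem-highest and stem-lowest transcripts numbered 2042, 994, 1311 and 3315. With a pseudocount of 0.1, leaf-highest, stem-highest and stem-lowest numbered 1954, 1271 and 4048, and with library totals without TMM 1700, 1185 and 4069. By construction of these settings, TMM was absent from all 3. Without the fold threshold, leaf-highest and stem-highest numbered 1751 and 3224. Leaving out each library in turn gave 3135 to 4740 root-highest transcripts, the lowest without root replicate 3. With root replicate 3 as the only root sample the count was 3257, so both fits with 1 root sample gave fewer. With a replicate block on the 9 libraries as deposited, the counts were 11215 for leaf against root, 12991 for stem against root and 6986 for leaf against stem, compared with 11910, 13609 and 7680 for those libraries without the block; on leaf and stem libraries only, the block gave 6402. Deviations of same-numbered leaf and stem libraries correlated weakly, at 0.0013, 0.093 and 0.067; leaf replicates 2 and 3 correlated best with the stem library of the same number and leaf replicate 1 with stem replicate 3 (0.054). Whether replicate numbers pair the libraries is left open, and root was not examined for this. Detection moved with its limit by construction: at 0.1 TPM it was 25128 in leaf and 23654 in stem, and at 5 TPM it was 13855 in leaf, 17453 in root and 11221 in stem. The top 10 transcripts held 15.0%, 14.6% and 16.9% of TPM in leaf, root and stem, and the top 1000 held 59.4%, 57.4% and 66.4%. Pearson correlations of log2(TPM + 1) were at least 0.972 within stem and 0.825 between root replicate 3 and the other root libraries, above the Spearman values. With a pseudocount of 0.1 they were at least 0.936 and 0.695, the latter below the Spearman value of 0.731. Root libraries had the lowest totals, and with 2 root samples low transcripts in root are the least precise.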

Other observations

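Tests on root replicates 1, 2 and 3 were chosen after those libraries had been compared; the tests on transcript length and on other splits of the samples were written before their results were seen.

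Root held more transcripts without any read in the other tissues than leaf or stem did. Of 9429 transcripts with at least 10 TPM in both root samples, 453 (4.80%) had 0 reads in the 6 leaf and stem libraries, which totalled 97412884 reads. The corresponding numbers were 11 of 9066 transcripts (0.121%) for leaf and 9 of 7573 (0.119%) for stem, where the other tissues, root included, totalled 79781785 and 63925175 reads. The criteria were unequal, since leaf and stem had to reach 10 TPM in all 3 libraries. Leaf and stem were also each set against the other shoot tissue, to which they were closer than to root. The counts depend on root replicate 3: with that library left out, an alternative chosen after seeing the data, they were 23 of 9066 (0.254%) for leaf, 16 of 7573 (0.211%) for stem and 655 of 11154 (5.87%) for root. Root then had to reach 10 TPM only in the mean of replicates 1 and 2. Whether the transcripts found in root alone belong to the plant or to another organism in the root samples was not tested, since no sequences were used. Conversely, of 6419 transcripts with at least 10 TPM in every leaf and stem library, 23 (0.358%) had 0 reads in the 3 root libraries. A further contrast lay inside root: 103 of those shoot transcripts had 0 reads in root replicates 1 and 2, and 80 of the 103 had reads in root replicate 3, with a median of 3.06 TPM in that library over the 103.

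Root replicates 1 and 2 were nearly equal. Independent reads, from separate plants or separate sequencing, would give a chi-square statistic per degree of freedom of 1 or more, and it was 0.527. Among 5744 transcripts with whole read numbers in both and at least 20 reads in the pair, replicate 2 exceeded replicate 1 in 1 (0.0174%), whereas the smaller library exceeded the larger in 26.6% to 41.9% in the other pairs examined. Over all transcripts with reads in either, including those whose reads Salmon divides among similar transcripts, replicate 2 was higher in 12.5%, lower in 54.2% and identical in 33.3%. Replicate 2 held 98.0% of the reads of replicate 1. This is consistent with the reads of replicate 2 being part of those of replicate 1, for example after a further filtering step, which is a hypothesis on the processing and was not settled here.

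Root replicate 3 detected more transcripts, mostly short ones at low levels. Greater depth does not account for it, since it held fewer reads than root replicates 1 and 2 (7117807 against 8093638 and 7935593, 0.888 times their mean). This comparison of totals replaced an earlier test by thinning, which was dropped because thinning to the smallest library leaves this library as it was. An even background such as genomic DNA would add similar TPM at all lengths. This was examined among transcripts with a shoot mean above 0 and below 0.5 TPM. Transcripts without shoot reads, and so those read in root replicate 3 alone, were left out. In this set the median added TPM was 1.74 in the length class that ends at 500 bases (from above 300). It was 0 above 2000 bases, a ratio of 0 (bootstrap 95% interval 0 to 0.04, 2000 resamples of transcripts). The interval shows the spread among transcripts and not between root samples, since 1 library was set against 1 averaged sample. The added TPM was not corrected for the common shift of root replicate 3 (median log2 -0.35 at 20 TPM or more). This shift lowers the added TPM of transcripts expressed in root. Above 2000 bases the median was 1.35 TPM in root replicate 3 and 0.92 in root replicates 1 and 2. The ratio therefore does not decide on an even background. RNA of another organism stays open because no sequences were used here: 2945 transcripts (median length 275 bases, median 3 reads) had reads in root replicate 3 alone, and they held 0.365% of its reads. A difference between plants, or a reference set assembled partly from this library, may also contribute, and neither was tested.

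In leaf against stem, short transcripts were more often higher in leaf, and leaf against root showed a similar fall with length (leaf higher in 62.5% of calls up to 300 bases and in 36.1% above 2000 bases), whereas stem against root did not (stem higher in 38.0% and 41.7%). The tests below were run on leaf against stem only. In that comparison leaf was higher in 69.7% of calls up to 300 bases and in 41.8% above 2000 bases, a gap of 27.9 percentage points (21.3 to 28.0 with a leaf or stem library left out). The tables argue against differences in effective length between libraries, since the gap was 28.0 points with effective-length offsets. They also argue against the greater read totals of the stem libraries, since the gap was 27.6 points after thinning to 12809484 reads. With TMM factors of 0.75 to 0.79 in stem and 1.12 to 1.14 in leaf, equal totals did not give equal library sizes after scaling. Libraries of equal scaled size were not compared. The gap and the majority depend on scaling. With library totals without TMM, leaf was higher in 85.1% of calls up to 300 bases and in 67.7% above 2000 bases (gap 17.4 points), and with limma on log2(TPM + 1) in 86.3% and 64.6% (21.7 points), so that above 2000 bases the majority was in leaf under these and in stem under TMM. The cause of the gap was not found, and a difference between the tissues themselves remains open and may be involved.

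Other splits of the samples gave fewer calls. For leaf against stem, the real grouping gave 7115 calls and the highest of the other splits gave 0 (edgeR; 431 transcripts at an unadjusted p under 0.05, against 11837), but with 10 splits, of which 1 was as large, a share under 0.05 cannot be reached. For the test over 3 tissues, 1 of 40 splits from the 280 possible, the real one, gave 17069 transcripts, and the highest other split gave 994. The real split was included by design. In both comparisons every other split puts samples of different tissues into 1 group, which widens the spread within groups. Fewer calls were therefore built into those splits, and no conclusion on chance is drawn from them.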
